A study of Mus musculus with 6 samples.

How the data were processed

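Primary spermatocytes were sorted by Hoechst staining and flow cytometry from testes of adult mice, RNA was taken up in Trizol and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. This kit does not mark strand, and whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The genotype in the labels put 3 libraries in each group.

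The deposited table holds estimated counts (RSEM expected counts), TPM and FPKM per gene and library, per the file headers. The submitters' processing notes name STAR 2.7.0f, RSEM 1.3.2, edgeR 3.28.1 and the builds GRCm39 and mm9, with no role given for each; the annotation release is not given in the sources used here. The expected counts were deposited without normalization and were rounded to whole numbers here. TPM and FPKM were computed by the authors per library and served here as an alternative scale and as a check on each other. The deposited files hold no coordinates. Positions, transcript lengths and 3' UTRs came from GENCODE M21 on GRCm38, matched by gene identifier; 52093 of the 53700 genes had a match, and the other 1607 held 0.278% of the counts. That build may differ from the one used for counting, which affects positions and UTRs but not the counts.

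Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, a quasi-likelihood F test on genotype and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 24 lists, and with fry. With the preset correlation 12 lists passed, with an estimated one 0 of the same 24 passed, and fry found 3 by direction and 12 in either direction. The estimated form is stricter apart from the correlation. The Leydig list had an estimated correlation of 0.009, below the preset one, yet its camera p went from 1.55e-06 to 0.00832. Other lists had estimates up to 0.904, and for such lists the preset correlation makes p-values too small. X-linked and miR-138-5p sets were tested the same way, the latter against genes with an annotated 3' UTR and no site, and against genes matched on UTR length and mean expression. Depth was 7400360 to 9294723 counts per library. Floors (3 counts) cover counting error only. The bootstrap interval given for X-linked spermatogonial genes resamples genes, so it does not measure the spread between libraries.

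The tests, gene lists and most alternatives were set before the data were examined. Named genes were Sry and H2ax, then the genes with the largest changes and smallest p past the threshold with a mean of at least 5 CPM in the higher group, an assigned symbol and separated groups (none passed), then for each list the 3 members with the smallest p or, where none passed, the 2 with the highest mean. Other genes were chosen after their values were seen. Alternatives were RLE and upper-quartile factors, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, a replicate block, each library left out in turn, a 2-fold minimum and limma on log2(TPM + 1) and log2(TPM + 0.1) for genes at 1 TPM or more in 3 libraries. Chosen after seeing the data were offsets that remove each library's lowess trend (span 0.3) on transcript length, limma-voom with sample quality weights, TPM recomputed from FPKM, the X-linked test without the X-linked ones of 9 genes whose deposited TPM and FPKM disagree (605 genes left), the Y-linked list with TPM recomputed from FPKM and without such genes, and an estimated correlation for the miR-138-5p set. Against the TMM scale the median log2 fold change of all genes, 0.12, moved by -0.14 with limma-voom, -0.12 with the replicate block, -0.10 without KO replicate 3 and by -0.38 and -0.46 on the 2 TPM scales.

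The edgeR steps were tested on simulated counts for the circSry KO against WT comparison over 16829 genes. With the spread of the 6 libraries they recovered 6% of genes changed 2-fold, 46% at 4-fold, 94% at 8-fold and 92% at 16-fold. With the spread of the 3 WT libraries they recovered 40% at 2-fold and 100% at 4-fold. Simulated genes of the same mean level shared the same spread, and no simulated library stood apart as KO replicate 3 does. In the data Cst12 and Cst9, at log2 fold changes of 4.23 and 4.45, did not pass in edgeR. The rates therefore do not show that 8-fold changes would have been found.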

Results

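RNA libraries had been sequenced from flow-sorted primary spermatocytes, the germ cells that carry out meiotic prophase, of adult C57BL/6 mice. The libraries formed 2 groups of 3: wild type (WT) and a knockout of circSry (circSry KO), the circular RNA made from the sex-determining gene Sry. The tables gave 7400360 to 8422943 estimated read counts per library in WT and 8191397 to 9294723 in circSry KO. Of 53700 genes listed, 16829 had enough counts to be tested. Replicates were separate samples by their labels, which do not say that each came from its own animal, so p-values measure only the spread between these 6 samples. Unless stated otherwise, expression is in CPM, counts scaled to library size, and differences are circSry KO against WT.

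Sry, on the minus strand of chromosome Y from 2662471 to 2663658 (GRCm38), had a count of 0 in each of the 6 libraries. A count of 0 allows up to 0.323 to 0.405 CPM per library, counting error only. A gene-level count does not measure the circular RNA, so the knockout could not be checked in these values.

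The question of the first comparison was which messenger RNAs differ between spermatocytes with and without circSry. The mean level of spermatid marker genes was higher in each of the 3 circSry KO libraries than in WT, and the mean level of several lists of meiotic genes was lower. No single gene passed an adjusted p of 0.05: edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.087. At an unadjusted p under 0.05 it found 3941 genes, 2285 higher and 1656 lower. DESeq2 called 935 higher and 679 lower after adjustment, limma-voom 0 and 0, and limma on log2(TPM + 1) 4 and 2. In 28.5% of the genes tested the 3 KO libraries lay entirely on one side of the 3 WT libraries, against 10% on average by chance. Genes vary together, so 1 shared shift can raise this share, and it is not a test. The count of 0 depended on circSry KO replicate 3, without which edgeR called 3319 genes higher and 2909 lower of 17948 tested. Of the 1614 DESeq2 calls, 1594 were among these. Leaving out the library that differed lowered the fitted coefficient of variation between replicates from 0.453 to 0.289. All p-values given without KO replicate 3 are therefore too small. Counts of list members called in that fit are to be read against its share over all genes.

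Under the conditions set for named genes other than the adjusted p, the 5 higher and 5 lower genes with the smallest p were chosen after their values were seen. So were the list members named below with a small p; the 2 most abundant members of each list were set by the rule. The 5 higher genes were Cst12, Cst9, Klk1b8, Cypt3 and Cypt1. Cst12 and Cst9 encode cystatins of the testis and lie on chromosome 2; Cst9 went from 0.847 ± 0.471 CPM in WT to 18.5 ± 7.15 in KO (SD, n = 3 each), a log2 fold change of 4.45 ± 0.58 (SE). Cypt1 and Cypt3 are X-linked genes of spermatids, with log2 fold changes of 2.47 ± 0.37 and 2.50 ± 0.38 (SE). Klk1b8, a kallikrein gene, had 2.84 ± 0.43 (SE). These 3 genes have near-identical relatives among which reads can be divided, so their values are uncertain. The 5 lower genes were Gigyf1, Hyou1, Cyp11a1, Cdc42bpg and Elfn2. Hyou1, a chaperone of the endoplasmic reticulum, went from 496 ± 58.2 to 114 ± 27.0 CPM (SD, n = 3 each), and its log2 fold change was -2.12 ± 0.32 (SE). Gigyf1, a factor in translational repression, had -2.33 ± 0.34 (SE). All 10 had an adjusted p of 0.087 in edgeR.

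**Figure D1:**
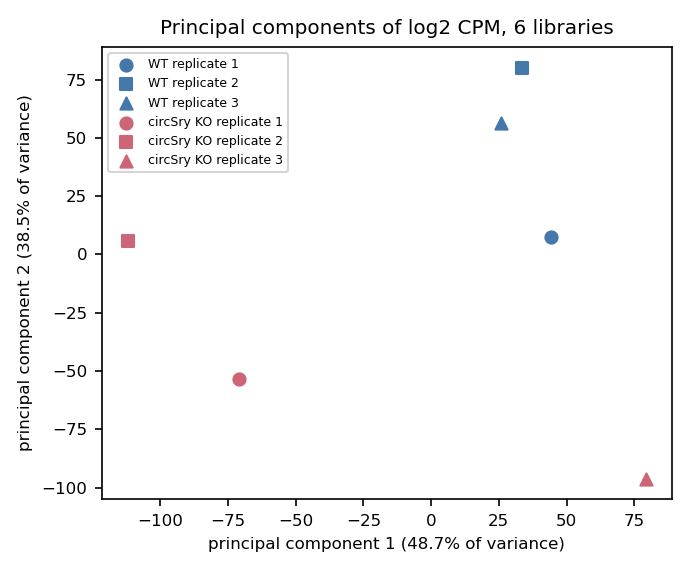
Principal components 1 and 2 of log2 CPM over the 16829 tested genes, one point per library (blue WT, red circSry KO), holding 48.7% and 38.5% of the variance. circSry KO replicate 3 lies at 79.36 on component 1, away from KO replicates 1 and 2 at -70.86 and -111.99.

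circSry KO replicate 3 stood apart from the other KO libraries. Its log2 CPM correlated across genes at 0.927, 0.846 and 0.875 with WT replicates 1, 2 and 3. With KO replicates 1 and 2 it correlated at 0.878 and 0.778, while those 2 correlated at 0.946. Genes are not independent replicates. It held 22202 genes with at least 1 count, fewer than the 23928 to 26121 of the other 5 libraries. Relative to the WT mean, its genes in the shortest quintile of transcript length lay at a median log2 of 1.10 and those in the longest quintile at -0.78. Smaller trends of this direction were present in KO replicate 1 (0.68 and -0.36) and WT replicate 1 (0.46 and -0.43), and WT replicate 2 had the opposite one (-0.37 and 0.35).

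The study's title concerns γH2AX, the phosphorylated form of the histone variant H2AX that marks DNA breaks and the silenced sex chromosomes. H2ax, on the plus strand of chromosome 9 from 44334694 to 44336077 (GRCm38), stood at 95.4, 111 and 86.5 CPM in the WT libraries and at 39.2, 18.1 and 142 CPM in KO replicates 1, 2 and 3. Group means were 97.5 ± 12.2 and 66.5 ± 66.4 CPM (SD, n = 3 each). The log2 fold change of -0.55 ± 0.66 (SE) was within the spread between replicates (edgeR adjusted p = 0.639). After the correction for transcript length it was -1.14 (edgeR adjusted p = 0.293). Without KO replicate 3 it was -1.81 with an edgeR adjusted p of 0.0039, where the alternatives as a whole ranged from 0.0039 to 0.912. That p-value is too small, since the library left out was the one that differed. All values are levels of the messenger RNA, and the phosphorylated protein was not measured.

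The list of 34 tested genes of the sex body and the γH2AX pathway fell as a group, with a mean log2 fold change of -0.58 (camera adjusted p = 8.65e-05; adjusted p = 0.458 with an estimated correlation). Over all genes tested 0 members passed in edgeR, 7 were lower and 1 higher at an unadjusted p under 0.05 and DESeq2 called 5 lower. Adjusted over the list alone, 4 members were lower (Mdc1, Topbp1, Setdb1 and Ago4) and 30 did not pass. Mdc1, the adaptor that binds γH2AX, stood at 608 ± 146 CPM in WT and 154 ± 40.0 in KO (SD, n = 3 each), a log2 fold change of -1.98 ± 0.34 (SE). Topbp1, which activates the kinase ATR, went from 155 ± 49.2 to 33.1 ± 6.58 CPM (SD, n = 3 each). The methyltransferase gene Setdb1 had a log2 fold change of -1.57 ± 0.33 (SE). Each of these 3 was lower in 3 of 3 KO libraries than in all WT libraries. Of the 2 most abundant members, Atr had -1.29 ± 0.40 and Ehmt2 -0.01 ± 0.30 (SE), the latter of either sign across scalings. Without KO replicate 3 the mean was -0.98 and 17 members were called lower and 1 higher (list adjusted p = 0.293 with an estimated correlation).

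**Figure D2:**
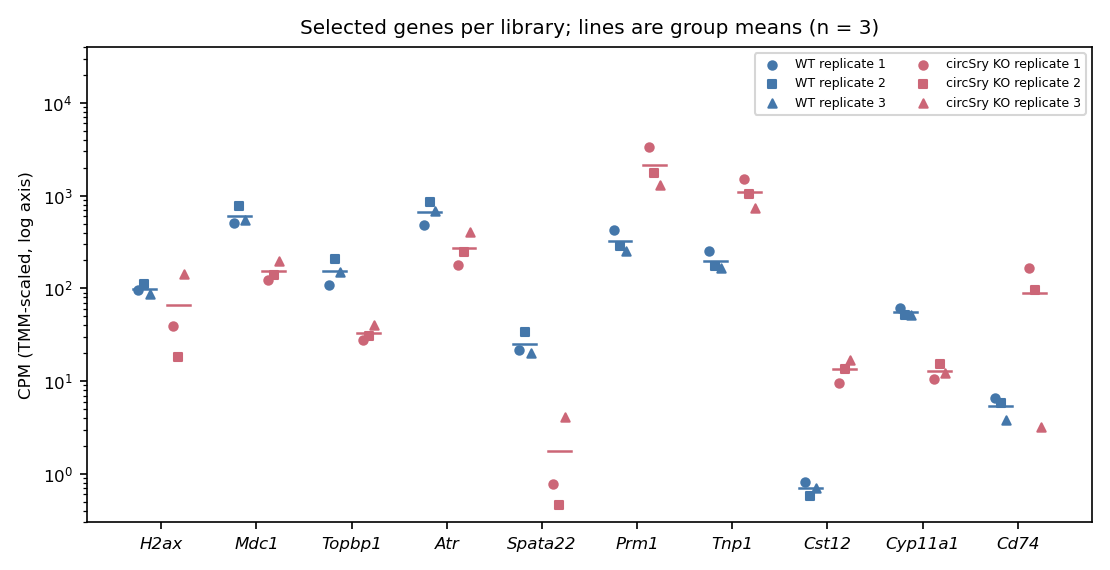
Expression of 10 genes in each library, in CPM on a log axis (blue WT, red circSry KO); horizontal lines are group means (n = 3). Mdc1, Topbp1, Atr, Spata22 and Cyp11a1 lie lower in all 3 KO libraries, Prm1, Tnp1 and Cst12 lie higher, and H2ax and Cd74 differ between KO replicate 3 and the other KO libraries.

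Other meiotic prophase genes moved with this list. Genes of double-strand break formation and recombination fell as a group (41 tested, mean log2 fold change -0.73, camera adjusted p = 2.01e-06; adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone 4 were lower (Spata22, Iho1, Shoc1 and Exo1); over all genes edgeR passed 0, with 11 at an unadjusted p under 0.05, and DESeq2 called 7. Spata22, required for meiotic recombination, was at 25.3 ± 7.77 CPM in WT and 1.77 ± 2.01 in KO (SD, n = 3 each). The most abundant members, Rpa1 and Cntd1, had log2 fold changes of 0.01 ± 0.33 (SE), of either sign across scalings, and -0.62 ± 0.49. Cntd1 stood at -1.47 without KO replicate 3 (edgeR adjusted p = 0.00382; range over the alternatives 0.00382 to 0.797). Synaptonemal complex and meiotic cohesin genes fell as a group (22 tested, mean -0.59, adjusted p = 0.00323; adjusted p = 0.458 with an estimated correlation; 1 lower adjusted over the list alone, 0 over all genes in edgeR, 8 lower and 1 higher at an unadjusted p under 0.05 and 3 lower in DESeq2). Sycp1, that 1 member, which forms the transverse filaments of the complex, had -1.72 ± 0.35 (SE), while Stag3 had -0.57 ± 0.28 and Syce1, of either sign across scalings, -0.004 ± 0.46. Preleptotene to zygotene markers fell as a group (18 tested, 17 with a negative fold change, mean -0.96, adjusted p = 9.88e-05; adjusted p = 0.243 with an estimated correlation; 0 past the threshold adjusted over the list alone, 7 at an unadjusted p under 0.05 in edgeR, 2 lower in DESeq2). Among them Meiosin, a regulator of meiotic entry, had -2.92 ± 0.84 and Ythdc2 -1.92 ± 0.47 (SE); the most abundant, Tex101 and Smc1b, had -0.20 ± 1.07 and -0.07 ± 0.27, the latter of either sign across scalings. Tex101 stood at -3.23 without KO replicate 3 (edgeR adjusted p = 0.000361; range over the alternatives 0.000361 to 0.991) and at 0.34 without KO replicate 2. Genes of the piRNA pathway, which silences transposons, fell as a group (25 tested, mean -0.70, adjusted p = 0.000333; adjusted p = 0.458 with an estimated correlation; 0 adjusted over the list alone, 8 lower and 1 higher at an unadjusted p under 0.05 in edgeR, 2 lower in DESeq2). Tdrd1 (-3.50 without KO replicate 3) and Piwil2 had -2.12 ± 0.70 and -1.79 ± 0.52 (SE), and the abundant Tdrd6 and Mael -0.29 ± 0.33 and -0.03 ± 0.31, both of either sign across scalings. KO replicate 3 lay nearer to WT than the other KO libraries in these 4 lists: its mean log2 CPM was 4.80 for recombination genes, against 4.89 to 5.18 in WT and 3.87 and 3.60 in KO replicates 1 and 2. Without it the means were -1.28 for recombination, -1.18 for synaptonemal, -1.45 for preleptotene to zygotene and -1.15 for piRNA genes (adjusted p = 0.293 with an estimated correlation for each). In that fit edgeR called 22, 12, 11 and 15 of them lower and 0, 0, 1 and 1 higher. The synaptonemal call was lost without KO replicate 2 (adjusted p = 0.0692; range over the alternatives 1.99e-05 to 0.458).

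Later germ cell stages went the other way. Elongating spermatid markers rose as a group, 29 of 29 with a positive fold change (mean 1.79, camera adjusted p = 4.41e-17; adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone 25 were higher and 4 did not pass; over all genes edgeR passed 0, with 25 at an unadjusted p under 0.05, and DESeq2 called 22. Prm1, a protamine that packs sperm DNA, went from 324 ± 92.8 to 2121 ± 1046 CPM (SD, n = 3 each), and the transition proteins Tnp1 and Tnp2 had log2 fold changes of 2.47 ± 0.38 and 2.37 ± 0.42 (SE). Odf2, the most abundant member, had 0.57 ± 0.37. After the length correction Prm1 was 1.70 against 2.71 before, Tnp1 1.43, Tnp2 1.49 and Odf2 0.77. All 3 KO libraries lay above all WT libraries for 18 of the 29 elongating and 24 of the 30 round spermatid genes. Chance gives 10% on average over both directions, but members of a list vary together, so these shares are not tests. Round spermatid markers rose as a group, 30 of 30 positive (mean 1.42, adjusted p = 1.09e-15; adjusted p = 0.38 with an estimated correlation), with 26 higher adjusted over the list alone, 26 at an unadjusted p under 0.05 in edgeR, 0 past the threshold over all genes and 17 in DESeq2. Tmco2 and Prss55 had log2 fold changes of 2.18 ± 0.38 and 2.02 ± 0.38 (SE), Actl7b 1.09 ± 0.39 and Zpbp2 0.63 ± 0.31. Pachytene and diplotene markers did not pass (35 tested, adjusted p = 0.327); their mean of -0.12, the side of the test, and their median of 0.12 differ in sign. Without KO replicate 3 the mean was -0.54 and the list passed at an adjusted p of 0.0218 (adjusted p = 0.53 with an estimated correlation; range over the alternatives 0.0218 to 0.98), and without KO replicate 2 the mean was 0.01. Sycp1 alone was lower adjusted over the list. Ldhc, a lactate dehydrogenase of male germ cells, had 0.35 ± 0.40 (SE), negative on the TPM scale and after a length correction, and Ybx2, a storage protein for germ cell mRNA, -0.92 ± 0.30. Meiotic division genes (41 tested, mean -0.16, adjusted p = 0.138; 0.0148 without KO replicate 3, and there adjusted p = 0.674 with an estimated correlation; range over the alternatives 0.0148 to 0.824) and spermatogonia markers (20 tested, mean 0.57 and slightly negative on the TPM scale, adjusted p = 0.0997, range over the alternatives 0.0162 to 0.458) did not pass. Spermatogonia markers passed in 2 of 18 alternatives, DESeq2 and no filter. In these lists Bub1b had -1.19 ± 0.30 (SE), Cdc20 -0.36 ± 0.40 (-0.90 without KO replicate 3, edgeR adjusted p = 0.0395; range over the alternatives 0.0395 to 0.927) and Aurka, negative on the TPM scale, 0.33 ± 0.34, and Gfra1 had 1.41 ± 0.39, Uchl1 0.99 ± 0.41 and Dmrtb1 -0.19 ± 0.35.

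**Figure D3:**
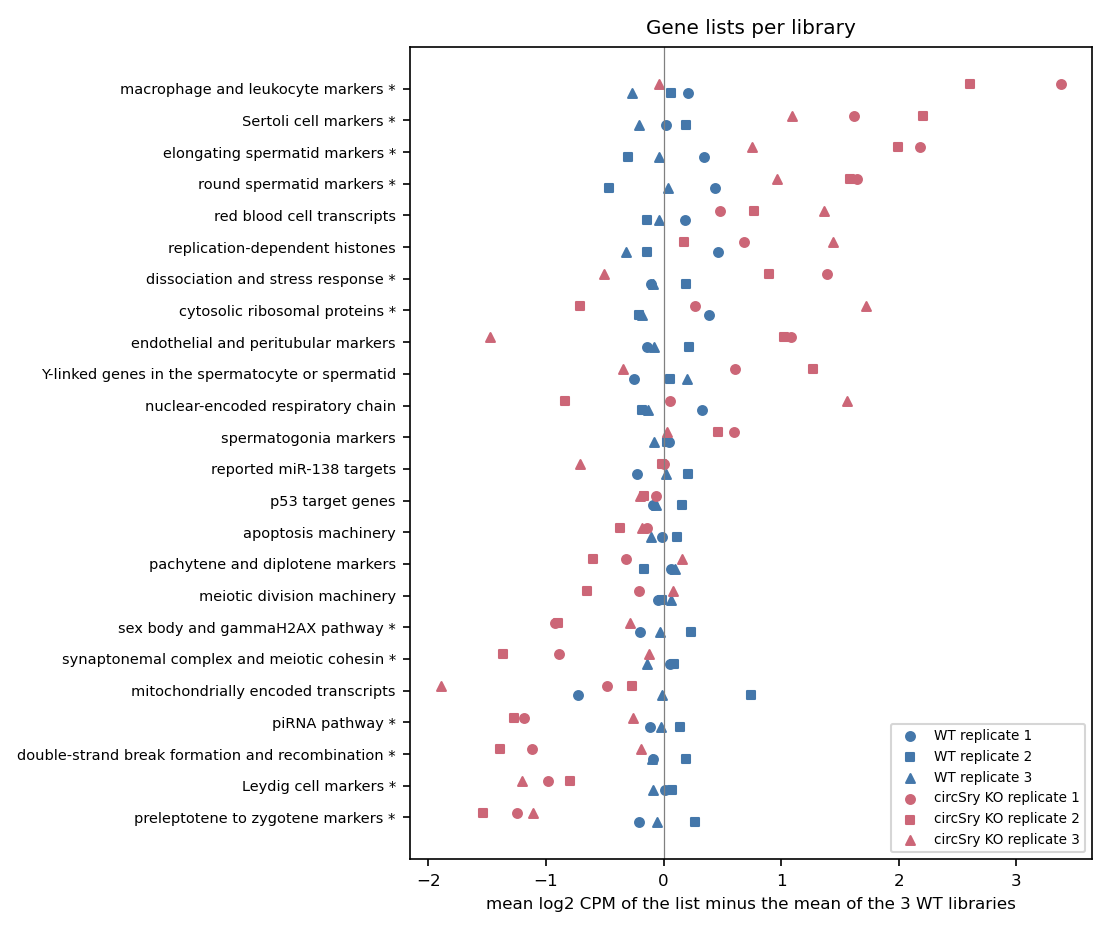
Mean log2 CPM of each of 24 gene lists per library, minus the mean of the 3 WT libraries (blue WT, red circSry KO; asterisks mark camera adjusted p under 0.05 with the preset correlation). The spermatid and Sertoli lists lie above WT and the Leydig and preleptotene lists below WT in all 3 KO libraries, while the leukocyte list is high in KO replicates 1 and 2 alone, and the ribosomal list is high in KO replicate 3, with a mean of -0.22 without it.

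Markers of somatic cells of the testis also differed. Sertoli cell markers rose as a group (23 tested of 30 listed, mean 1.94, camera adjusted p = 7.22e-12; adjusted p = 0.243 with an estimated correlation), with 17 higher adjusted over the list alone, 0 over all genes in edgeR, 17 at an unadjusted p under 0.05 and 11 in DESeq2. Amhr2, a receptor for anti-Müllerian hormone, had a log2 fold change of 2.01 ± 0.36 (SE), Cst12, also on this list, 4.23 ± 0.47 and Clu 1.52 ± 0.35, while Tjp1, a tight junction gene of many epithelia, had -0.38 ± 0.55. Leydig cell markers fell as a group (18 tested, mean -0.87, adjusted p = 6.19e-06; adjusted p = 0.2 with an estimated correlation), 6 adjusted over the list alone, 0 over all genes in edgeR, 9 at an unadjusted p under 0.05 and 6 in DESeq2. Cyp17a1 and Cyp11a1, enzymes of androgen synthesis, went from 115 ± 6.74 to 36.6 ± 9.19 CPM and from 55.0 ± 5.66 to 12.8 ± 2.50 CPM (SD, n = 3 each). Hsd3b1 had a log2 fold change of -1.62 ± 0.37 (SE) and Insl3 -0.60 ± 0.51, or -1.38 without KO replicate 3 (edgeR adjusted p = 0.0137; range over the alternatives 0.0137 to 0.847) and -1.66 after the length correction. Macrophage and leukocyte markers rose as a group (17 tested, mean 2.69, adjusted p = 1.39e-06; adjusted p = 0.458 with an estimated correlation), 13 higher adjusted over the list alone, 0 over all genes in edgeR, 13 at an unadjusted p under 0.05 and 14 in DESeq2. The level lay in 2 of the KO libraries: Cd74, the class II invariant chain, stood at 167 and 97.0 CPM in KO replicates 1 and 2, at 3.19 in replicate 3 and at 3.85 to 6.60 in WT. H2-Aa and C1qb had log2 fold changes of 4.64 ± 1.10 and 3.24 ± 0.77 (SE), and Apoe 1.48 ± 0.75, or 0.45 to 2.07 over left-out libraries. Endothelial and peritubular markers did not pass (25 tested, mean 0.70, adjusted p = 0.43; test downward without KO replicate 1 or 2, at means of 0.36 and 0.39 and adjusted p of 0.55 and 0.786), but 13 were called higher without KO replicate 3 (list adjusted p = 0.000205; adjusted p = 0.293 with an estimated correlation; range over the alternatives 0.000205 to 0.827). Dcn stood at 242 and 255 CPM in KO replicates 1 and 2, at 13.7 in replicate 3 and at 18.4 to 34.1 in WT; Col1a2 had 1.98 ± 0.85 (SE) and Sparc, of either sign across scalings, 0.20 ± 0.52. Members at an unadjusted p under 0.05 numbered 3 in edgeR, and DESeq2 called 1.

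Of the lists of cell state, genes of dissociation and stress rose as a group (25 tested, mean 0.91, camera adjusted p = 0.0225; adjusted p = 0.568 with an estimated correlation), with 0 past the threshold adjusted over the list alone, 6 at an unadjusted p under 0.05 in edgeR and 2 in DESeq2. The call was lost without KO replicate 1 or 2, at means of 0.49 and 0.87 and adjusted p of 0.245 and 0.0586 (range over the alternatives 2.53e-06 to 0.568). The mean was 1.39 without WT replicate 2 and 1.57 without KO replicate 3 (adjusted p = 0.293 with an estimated correlation). Klf6 and Jund had log2 fold changes of 1.88 ± 0.66 and 1.24 ± 0.39 (SE), Hsp90aa1 -0.24 ± 0.34 and Dnajb1, negative on the TPM scale, 0.16 ± 0.32. Cytosolic ribosomal proteins rose as a group (85 tested, mean 0.76, adjusted p = 0.00323; adjusted p = 0.736 with an estimated correlation; 0 adjusted over the list alone, 5 at an unadjusted p under 0.05 in edgeR and 1 in DESeq2), but their mean was -0.22 without KO replicate 3 (adjusted p = 0.0909; range over the alternatives 9.09e-14 to 0.736), 1.15 without KO replicate 2 and -0.03 on the TPM scale. Rpl13 had 0.69 ± 0.73 (SE) and Rplp0 0.41 ± 0.47, both negative on the TPM scale, and the X-linked Rps4x 1.47 ± 0.45; genes of this family share reads with pseudogenes. Nuclear-encoded respiratory chain genes did not pass (81 tested, mean 0.62, adjusted p = 0.0628). They passed upward without WT replicate 1, KO replicate 1 or KO replicate 2 (adjusted p of 0.0297, 0.00183 and 3.93e-09) and downward without KO replicate 3 (mean -0.41, adjusted p = 0.0063; adjusted p = 0.74 with an estimated correlation; range over the alternatives 3.93e-09 to 0.793). Mitochondrially encoded transcripts did not pass (13 tested, mean -0.66, adjusted p = 0.0504), but did in 11 of 18 alternatives, among them those without WT replicate 1 or 3 or KO replicate 1 or 2 (0.00271, 0.0173, 0.00987 and 0.0197; range over the alternatives 4.3e-05 to 0.547). The length correction gave them a mean of -1.48 and an adjusted p of 4.3e-05. Cox4i1, negative on the TPM scale, had 0.73 ± 0.74, Atp5b -0.23 ± 0.31, mt-Co1 -0.89 ± 0.76 and mt-Co2 -0.27 ± 0.31 (SE). Genes of the p53 response (30 tested, mean -0.09, adjusted p = 0.323) and of apoptosis (30 tested, mean -0.10, adjusted p = 0.162) did not pass, with means of either sign across the alternatives. Ppm1d, a phosphatase that acts on γH2AX, had 1.06 ± 0.33 (SE) and Mdm2 -0.22 ± 0.28; the apoptosis genes Bcl2l11 and Bak1 had 1.87 ± 0.48 and -1.37 ± 0.32, Bcl2l1 -0.30 ± 0.41 and Diablo, of either sign across the alternatives, -0.16 ± 0.60. Without KO replicate 3 Bcl2l1 stood at -0.86 and Diablo at -1.28 (edgeR adjusted p of 0.0459 and 0.0154; ranges over the alternatives 0.0459 to 0.956 and 0.0154 to 0.999). Red blood cell transcripts (6 tested, mean 1.08, adjusted p = 0.0689, 0.0138 without KO replicate 1, range 0.0138 to 0.485) and replication-dependent histones (7 tested, mean 0.93, of either sign across scalings, adjusted p = 0.0504) did not pass. The histones passed without WT replicate 1, KO replicate 1 or KO replicate 2 (0.0297, 0.0254 and 0.0121; range 0.0121 to 0.803). Without KO replicate 3 their mean was 0.35 (camera adjusted p = 0.484), and after the length correction 0.04 (camera adjusted p = 0.803). Bpgm had 0.52 ± 0.31 (SE), Fech, of either sign across scalings, -0.36 ± 0.35, H4c1 1.42 ± 0.35 and H3c1 2.02 ± 0.48. Adjusted over the list alone, the X-linked Alas2 and the histone genes H4c1 and H3c1 were higher; histone copies share sequence, so their counts are uncertain. With an estimated correlation 0 of the 24 lists passed, whichever library was left out. That form of the test is stricter apart from the correlation, so these losses alone do not show that correlation between genes removed the calls. The estimated correlation ran from 0.009 for the Leydig list to 0.904 for the ribosomal list. It was 0.753 for leukocyte, 0.607 for elongating spermatid and 0.521 for round spermatid markers. For lists so far above the preset 0.01, the p-values with the preset correlation are too small.

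Silencing of the sex chromosomes in pachytene cells depends on γH2AX, which made X-linked genes the next comparison. As a set, 609 tested X-linked genes rose against 16072 autosomal genes: their mean log2 fold change was 0.77 against 0.13, a difference of 0.64 (camera p = 1.93e-09; p = 0.263 with an estimated correlation). Of the X-linked genes, 27.6% had all 3 KO libraries above all WT libraries and 2.46% below, against 13.4% and 14.9% of autosomal genes. Chance gives 10% on average over both directions, but X-linked genes vary together (estimated correlation 0.248), so these shares are not tests. Over all genes edgeR called 0 X-linked genes, 177 were higher and 6 lower at an unadjusted p under 0.05, and DESeq2 called 93 higher and 1 lower. The difference lay in KO replicates 1 and 2, in which the X-linked median stood 0.78 and 1.10 above the autosomal one relative to WT, while KO replicate 3 was at -0.02 and the WT libraries lay between -0.04 and 0.05. X-linked genes took 0.450, 0.548 and 0.503% of the counts in WT and 1.00, 1.18 and 0.439% in KO (means 0.5003 ± 0.0493% and 0.875 ± 0.388%, SD, n = 3 each; exact two-sided permutation p = 0.4, where 0.1 is the smallest possible). Without KO replicate 3 the set difference was 0.90 (camera p = 3.26e-12; p = 0.00378 with an estimated correlation; range over the alternatives 3.26e-12 to 0.475), and 270 of 683 X-linked genes were called higher and 11 lower. Y-linked genes expressed in spermatocytes or spermatids did not pass as a list (11 tested, mean 0.68, adjusted p = 0.0667, range over the alternatives 0.0187 to 0.692), though they did on both TPM scales (0.0187 and 0.0203) and after the length correction (0.033). Of the 11 genes, 5 have deposited TPM and FPKM values that disagree in KO libraries (Zfy1, Zfy2, Kdm5d, Ddx3y and Eif2s3y). TPM recomputed from FPKM rests on the FPKM of these genes, which is doubtful for Zfy1 in KO replicate 3. With it the adjusted p on log2(TPM + 1) was 0.0473. For the other 6 genes alone the adjusted p was 0.147 on counts, 0.121 on log2(TPM + 1) and 0.213 after the length correction. The mean log2 CPM of the list was 3.23 and 3.89 in KO replicates 1 and 2 and 2.28 in KO replicate 3, against 2.37 to 2.82 in WT. Y-linked genes took 0.0387, 0.0287 and 0.0341% of the counts in WT and 0.0824, 0.0836 and 0.0527% in KO (exact permutation p = 0.1, the smallest possible). Uba1y had a log2 fold change of -0.52 ± 1.03 (SE) and Eif2s3y 1.14 ± 0.32, the latter uncertain as 1 of these 5.

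**Figure D4:**
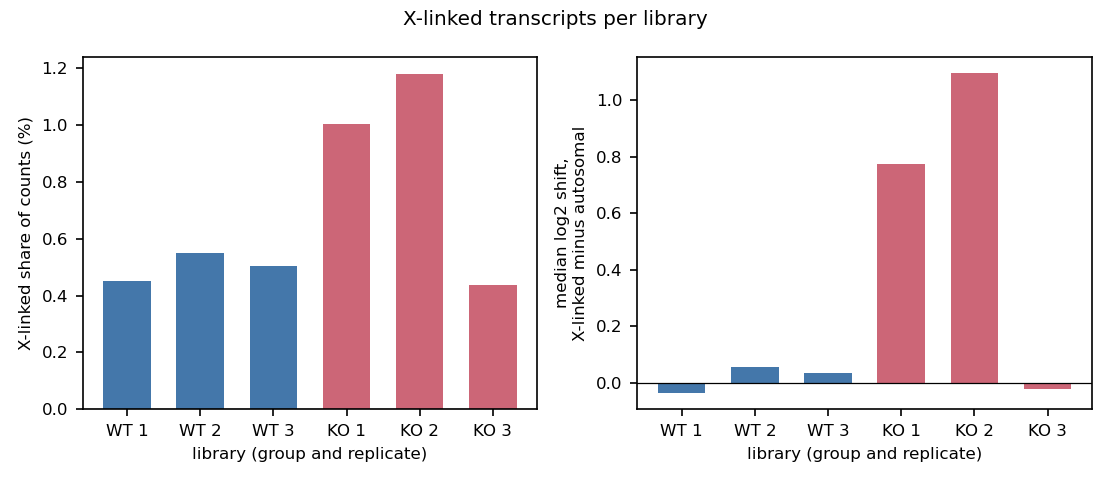
Left, share of each library's counts from X-linked genes in percent; right, median log2 shift of 609 X-linked genes minus that of autosomal genes, against the mean of the WT libraries (for a WT library, of the other 2). KO replicates 1 and 2 stand at 1.00 and 1.18%, and KO replicate 3 at 0.439%, below the 3 WT libraries.

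The title also names miR-138-5p, a microRNA that circSry was reported to bind, so transcripts with its sites were compared with the rest. The 2173 tested genes with an 8-mer or 7mer-m8 site in the annotated 3' UTR had a mean log2 fold change of -0.07, against 0.14 in 11767 genes with a UTR and no site, a difference of -0.20 (camera p = 0.0177; p = 0.295 with an estimated correlation). Against genes matched on UTR length and expression the difference was -0.05 (camera p = 0.52 with the preset correlation), after the length correction -0.03 (camera p = 0.668) and without KO replicate 3 -0.12 (camera p = 0.285; range over the alternatives 0.00142 to 0.668). With 8-mer sites alone (801 genes) and the unmatched background it was -0.25 (camera p = 0.00579 with the preset correlation). The 884-nucleotide 3' UTR annotated for H2ax held 0 8-mer and 0 7mer-m8 sites and 1 7mer-A1 site. Reported miR-138 targets did not pass as a list (26 tested, mean -0.06 and of either sign across scalings, adjusted p = 0.162), nor did any member adjusted over the list alone in edgeR, with 3 lower at an unadjusted p under 0.05 and 0 in DESeq2. Sirt1 and Lcn2 had log2 fold changes of -1.08 ± 0.37 and -1.11 ± 0.39 (SE), Aldh1a2 -0.78 ± 0.30 and Pdpk1 0.20 ± 0.53.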

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

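The tests of a few genes, of the X-linked spermatogonial genes and of the germ cell stages, the length correction, the X-linked test without genes whose TPM and FPKM disagree, and the comparison of gene lists for a wrong label were chosen only after the result was seen.

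Within each library the deposited FPKM was a constant multiple of the deposited TPM, within rounding, except for 11 values, which lay in KO replicates 1 and 3 alone, against 0 in the WT libraries. They belonged to 9 X- or Y-linked genes: 2 values in KO replicate 1 (Zfy1 and Zfy2) and 9 in KO replicate 3, among them Pgk1, Cul4b, Rbbp7 and Ddx3y. In 10 of the 11 values the TPM was above the value implied by FPKM, as for Rbbp7 in KO replicate 3 with 103 against 64.4 TPM. The TPM of KO replicate 3 summed to 1000152. A second deposited TPM table differed from the first in 1 value, Zfy1 in KO replicate 3, at 2.80 in place of 0.81. No explanation was tested. The transcript length implied by count and FPKM in KO replicate 3 lay outside the range of the other 5 libraries for 7 of the 9 genes, below it for 6 and above it for 1. For Zfy1 it was 815 nucleotides against 2544 to 2626. Of 6330 other genes with enough counts 28.5% lay below and 30.1% above. The implied length of Zfy2 was 2582 and 2601 nucleotides in KO replicates 1 and 3, against 2576 to 2608 in WT. That of Zfy1 in KO replicate 1 was 2588, against 2544 to 2617 in WT. For these values count and FPKM matched, and the TPM was out of step. The Zfy1 FPKM in KO replicate 3, 2.80, equals the second table's TPM, so its recomputed TPM of 2.54 is doubtful. Whether the counts of the 9 genes are as first estimated could not be checked, and TPM recomputed from FPKM rests on the FPKM of these genes. The X-linked comparison rests on counts, and without these genes its difference was 0.64.

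circSry KO replicate 3 stood apart from KO replicates 1 and 2, and leaving it out raised the calls from 0 to 6228. Its excess of short transcripts was not the whole cause, since a correction for transcript length left 0 calls over the 6 libraries and 7556 without it. Leukocyte or connective-tissue RNA in KO replicates 1 and 2 stays open. Leaving out the 286 genes at least 4-fold up in both hardly moved the correlations across genes (length-corrected log2 differences from the WT mean). They went from 0.833 to 0.818 between the 2 and from 0.312 to 0.31 at most with KO replicate 3. KO replicate 3 thus stayed apart over the 16543 genes that remained. Leaving out 286 of 16829 genes could move such correlations little, and smaller rises from such RNA were not left out. The test therefore could not tell. A wrong label stays open. Among genes with KO replicates 1 and 2 beyond the WT range, KO replicate 3 lay beyond that range on their side 1.31 times as often as on the other. WT libraries left out in turn gave 0.67 to 2.15, on both sides of 1. Their range came from 2 WT libraries in place of 3, so the ratios are not alike and could not tell. By the prediction set for it, that ratio alone would have fit a wrong label. Once it had been seen, gene lists were compared too, without a WT library left out for comparison. There KO replicate 3 followed the other KO libraries in 10 of 18 lists, opposed them in 5 and lay within the WT range in 3. A difference between knockout animals was not tested.

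X-linked transcripts were higher in KO replicates 1 and 2. This was not down to a few genes, since the median X-linked gene was shifted by at least 0.776 in each. A general loss of X silencing and RNA of other cells, such as leukocytes, connective tissue or late spermatids, cannot be told apart here. X-linked genes listed for spermatogonia had a median shift of -0.159, with a 95% bootstrap interval from -0.528 to 1.19 over 11 genes, too wide to separate these causes. Whether late spermatids or other such cells also express these genes was not checked, which limits the test further. An effect of the genotype was not tested apart from these. The sort should remove such cells, but Cd74 reached 167 CPM and Dcn 255 CPM in these libraries.

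The mean levels of the spermatid lists were higher and that of the early meiotic list lower in the KO libraries. Transcript length was not the whole cause, since the elongating spermatid mean was 1.44 after the correction against 1.79 before, and the preleptotene to zygotene mean was -1.0 against -0.96. A different mix of germ cell stages in the sort and an effect of the genotype cannot be told apart, since 9 of 9 values of these 3 lists lay outside the WT range in the KO libraries, as both would give. Leydig markers fell while Sertoli markers rose. A smaller share of spermatocytes would not give both if it raised all other cell types alike. Whether the mix of other cells differed between sorts was not tested, so this stays open.

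For the 10 splits of the 6 libraries into 3 and 3, no share under 0.05 is possible. The real split gave 0 genes and the highest other 0, with all 10 splits as large. It gave 12 lists and the highest other 17; 6 splits, the real one included, gave at least 12. It gave an X-linked difference of 0.642 and the highest other 0.663; 3 splits, the real one included, gave at least the real value, and each of these put KO replicates 1 and 2 on one side, which points to a structure of the samples. For the miR-138-5p set it gave a difference of 0.204 in size and the highest other 0.253; 2 splits, the real one included, gave at least the real value. At an unadjusted p under 0.05 the real split gave 3941 genes and the highest other 2182.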

How the results depend on the processing

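The length correction, quality weights, recomputed TPM, reduced X- and Y-linked sets, estimated correlation for the miR-138-5p set and estimated correlation with a library left out were tests chosen after seeing the data. The gene counts depended on the test and on 1 library. DESeq2 gave 935 higher and 679 lower, no filter 548 and 321, limma 4 and 2 on log2(TPM + 1), with TPM recomputed from FPKM as well, and 4 and 3 on log2(TPM + 0.1), and limma-voom with quality weights 5058 and 4922; the other alternatives apart from left-out libraries gave 0. The quality weights were 5.532 for WT replicate 3 and 4.402 for KO replicate 1, against 0.129 to 1.111 for the other libraries. The weighted calls thus rest mostly on 1 library per group. Left-out libraries gave 0 to 3319 higher and 0 to 2909 lower, the high values without KO replicate 3. The 12 lists became 0 with an estimated correlation, over the 6 libraries and with any 1 left out, and 12 to 15 under the alternatives at the preset correlation, all run with camera or its preranked form; fry, another test, gave 3 by direction. The X-linked difference of 0.64 kept its sign in all 26 alternatives. It lost its call with an estimated correlation over the 6 libraries (0.642, p = 0.263) and without WT replicate 1, 2 or 3 (0.626, 0.668 and 0.64) or KO replicate 1 or 2 (0.539 and 0.469, with p up to 0.475), and kept it without KO replicate 3 (0.902, p = 0.00378) and in all others. The miR-138-5p difference lost its call with an estimated correlation (-0.204), after the length correction (-0.029), against the matched background (-0.047) and without KO replicate 3, with left-out libraries from -0.289 to -0.12. H2ax ranged from -1.81 to -0.11 over left-out libraries. Why calls differ between tools was not tested. The matched background changes the UTR length, expression and number of the genes compared with (2173 in place of 11767). The replicate block gave 0 calls and moved the lists to 13. Same-numbered libraries did not consistently deviate together (correlations 0.035, 0.334 and -0.272). Deviations from means of 3 libraries depend on each other, so these values cannot exclude that the numbers pair libraries. Sry had no value under any alternative. In simulated counts at this depth and spread 2-fold changes were mostly not detectable, and in the data larger ones did not pass in edgeR either.

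The genes and lists below changed sign, and the cause was not tested. Several have reported values well away from 0, such as Cox4i1 (0.73), Rpl13 (0.69) and the ribosomal and respiratory lists (0.76 and 0.62). After the length correction Ehmt2 was 0.163, Diablo 0.002, Smc1b 0.103, Ldhc -0.118, Fech 0.093, Tdrd6 0.062, Rplp0 -0.102 and Cox4i1 -0.319, and the means of the ribosomal and respiratory lists, tested downward against the other genes, were 0.114 and -0.023. On log2(TPM + 1) and log2(TPM + 0.1), Ehmt2 was 0.006 on both, Rpa1 -0.776 and -0.78, Ldhc -0.157 on both, Sparc -0.422 and -0.444, Dnajb1 -0.245 and -0.246, Aurka -0.133 and -0.134, Rplp0 -0.259 on both, Rpl13 -0.288 and -0.289 and Cox4i1 -0.288 on both. With limma-voom Ehmt2, Rpa1 and Sparc were 0.026, -0.011 and -0.057, with the replicate block 0.024, -0.011 and -0.04. Rpa1 was -0.029 in DESeq2 and -0.034 with no filter. Syce1 was 0.001 with RLE factors; upper-quartile factors gave Ehmt2 0.084, Syce1 0.045, Smc1b 0.025 and Mael 0.084. Over left-out libraries Ehmt2 ranged from -0.194 to 0.185, Rpa1 -0.208 to 0.214, Syce1 -0.452 to 0.482, Diablo -1.285 to 0.253, Dmrtb1 -0.42 to 0.094, Tex101 -3.231 to 0.335, Ldhc -0.142 to 0.604, Sparc -0.311 to 0.571, Dnajb1 -0.014 to 0.321, Mael -0.208 to 0.086, Pdpk1 -0.322 to 0.54, Rplp0 -0.308 to 0.735, Rpl13 -0.688 to 1.155, Cox4i1 -0.746 to 1.195 and Uba1y -1.924 to 0.002. List means ranged from -0.536 to 0.014 for pachytene markers, 0.358 to 1.057 for endothelial markers (tested downward without KO replicate 1 or 2), -0.218 to 1.154 for ribosomal proteins and -0.405 to 0.996 for the respiratory chain. Of the other values, 142 single-gene and 33 list values passed a threshold they had not passed, 18 list values no longer passed, and 1323 gene and 378 list values kept their side.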
